A study of Homo sapiens with 12 samples.

How the data were processed

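Gene expression was measured by RNA sequencing of total RNA from 12 libraries of the MDA-MB-468 cell line, 3 each from control, SAHA (10 µM, 12 h), sonidegib (10 µM, 72 h) and the combination. Groups and replicate numbers were taken from the sample labels. RNA was extracted with TRIzol and libraries followed a standard Illumina protocol per the labels. Whether the RNA was selected by poly(A) tail or depleted of ribosomal RNA, and whether libraries were stranded, was not stated, so values of genes that overlap on opposite strands are uncertain. Whether the groups were prepared together was not stated either.

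The deposited table held TPM in one column per library, rounded to 2 decimals. The authors had scaled each library over all genes after a correction for transcript length. Bowtie2 2.4.1 and the genome build GRCh38 were named by the submitters; the quantifier, the annotation release and any filter were not stated. Each column summed to between 999999 and 1000001 TPM, and no library was identical to another. Since TPM keep no counts, the depth per library is unknown, and no counting interval was computed. Of the gene identifiers 58611 matched GENCODE release 29, which supplied gene type, chromosome, start, end, transcript length and GC content, and 713 did not. Of these 440 had no name and carried identifiers that transcript assemblers give to loci outside an annotation. Gene symbols are those of the table. Coordinates refer to GRCh38.

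Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3. The 13937 genes with a mean of at least 1 TPM over the 12 libraries were tested, 11995 of them protein-coding, out of 29345 genes above 0 in at least one library. A model with 4 group means and 8 residual degrees of freedom was fitted, with variances moderated by an intensity trend (lmFit, contrasts.fit, eBayes). The comparisons were each drug and the combination against control, the combination against each drug, and the interaction, defined as combination minus sonidegib minus SAHA plus control. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The effects of SAHA with and without sonidegib, and of sonidegib with and without SAHA, share no libraries; they were compared across all tested genes by Pearson and Spearman correlation and by a total least squares slope, with a jackknife over the 12 libraries for the SE.

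The 41 gene lists held 752 symbols, 1 of which was not found: Hedgehog pathway; zinc-dependent histone deacetylases; histone acetyltransferases; S phase and replication; G2/M and mitosis; CDK inhibitors and growth arrest; pro-apoptotic and anti-apoptotic genes (2 lists). Further lists were homologous recombination and crosslink repair, cholesterol synthesis and uptake, fatty acid synthesis, amino acid response (ATF4 targets), endoplasmic reticulum chaperones, cytosolic heat shock proteins, NRF2 targets, metallothioneins, lysosome and autophagy, glycolysis, nuclear-encoded oxidative phosphorylation, MYC and ribosome biogenesis, interferon-stimulated genes, class I antigen presentation, NF-kB and inflammatory cytokines. Others were EGFR and MAPK signalling, Wnt pathway, Notch pathway, TGF-beta targets, epithelial, mesenchymal, basal epithelial and luminal epithelial genes, and stem cell genes. The remaining lists were drug efflux transporters, neuronal genes, replication-independent histones, hypoxia, mitochondrially encoded mRNAs, ribosomal proteins, leukocyte markers, fibroblast and endothelial markers, and erythroid and hepatic markers. The 39 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the lists of a comparison. A camera test compares a list with all other genes. An estimated correlation and fry, which asks whether a list's own genes move one way on balance, were the alternatives, with p-values adjusted in the same way. For these lists, a p given with an estimated correlation is such an adjusted p.

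The lists, the comparisons, the tests and the rule for naming genes were set before the data were examined. Named genes were, per comparison, the 8 largest rises and 8 largest falls (5 and 5 for the interaction and for the combination against a single drug) among called protein-coding genes with a mean of at least 5 TPM in a compared group and no overlap between the libraries of the groups compared (overlap was allowed for the interaction). Up to 2 rises and 2 falls per list and fixed genes were added, among them GLI1, GLI2, PTCH1, SMO, HHIP, HDAC1, HDAC2, HDAC3, HDAC6, CDKN1A, MYC, EGFR, BCL2L11, ABCB1, ABCG2, ACTB and GAPDH. Not every gene that met the rule is named in the text. Lists of splicing factors, of mRNAs with a 5' terminal oligopyrimidine tract and of RNAs without a poly(A) tail were added after values had been seen. Their camera p-values were not adjusted.

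Gene values, counts and effect comparisons were recomputed with another pseudocount (0.1 or 5), without the filter or with a mean of at least 5 TPM, with median-of-ratios, 75th percentile or quantile scaling, and with mitochondrial genes removed. They were also recomputed with the libraries of the compared groups alone, without the variance trend, with library weights, with the replicate number as a block, and without each library in turn. Lists were recomputed at a pseudocount of 0.1, at a mean of at least 5 TPM, after median-of-ratios scaling, with the block and without each library in turn. Protein-coding genes alone, rescaled to the same total, and the omission of the 2 libraries richest in ribosomal and small nuclear RNA were added after seeing the data. Trends of each library with GC content and length were removed in a further test, on the 97.8% of genes with both values. Group labels were exchanged in all 10 splits of each pair of groups and in 100 groupings for the interaction.

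The procedure was tested on simulated data of the same size. For SAHA against control it recovered 32% of the genes given a log2 change of 0.5, 86% at 1 and 96% at 2, with 8 false calls, and for the interaction 20%, 80% and 96%, with 3 false calls. At each size 50 of 13937 genes were changed, far fewer than were called in the data, so these shares need not hold there. In a simulation of 39 lists with 3 shifted by 0.3, camera called these 3 and also 2 lists that had not been shifted. No per-sample column of the table was left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.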

Results

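RNA sequencing measured gene expression in MDA-MB-468, a human triple-negative breast cancer cell line that carries extra copies of EGFR. SAHA (vorinostat) inhibits zinc-dependent histone deacetylases, and sonidegib inhibits Smoothened (SMO), the membrane protein that passes the Hedgehog signal into the cell. The 12 libraries formed 4 groups of 3: control, SAHA (10 µM, 12 h), sonidegib (10 µM, 72 h) and a combination, for which the labels describe sonidegib as a pretreatment. The labels do not state how long the control cells were kept or whether sonidegib remained present during the SAHA treatment. They also do not state whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical in origin. Values were TPM, a length-corrected share of all transcripts, which keep no record of read depth, so the depth of each library is unknown. Between 20125 and 21402 genes were above 0 in each library, and between 13204 and 13874 reached 1 TPM. In every comparison limma tested 13937 genes with a mean of at least 1 TPM over the 12 libraries. Changes are given as log2 fold changes of TPM + 1 with their standard error (SE), and levels as mean TPM with the standard deviation (SD), with n = 3 libraries per group. Largest changes are those among called protein-coding genes with a mean of at least 5 TPM in a compared group and, except for the interaction, no overlap of libraries. The added 1 makes changes of genes at a few TPM appear smaller than they were.

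The groups separated along the first 2 principal components, which held 35.2% and 29.1% of the variance. Across genes, libraries of the same group correlated at 0.967 to 0.980 and libraries of different groups at 0.906 to 0.956 (genes are not independent replicates). Mitochondrial ribosomal RNA differed between the groups, with a mean share of TPM of 0.616% in control, 1.24% with SAHA, 2.22% with sonidegib and 2.61% with the combination. The 17 annotated copies of 5S ribosomal RNA were listed at 0 in all 6 libraries without sonidegib and summed to between 1488 and 12641 TPM in the 6 libraries with it. The other ribosomal RNA genes of the nucleus summed to between 8924 and 15249 TPM without sonidegib and between 2642 and 14083 TPM with it. Whether the libraries with and without sonidegib were prepared and processed alike was not stated. Every cell makes 5S ribosomal RNA, so its listing at 0 in all 6 libraries without sonidegib points to a difference in preparation or processing. How far this difference reached other genes cannot be told apart from the treatment in comparisons across these sets of libraries. SAHA against control and the combination against sonidegib each compare libraries within a set, whereas the interaction compares SAHA responses across the sets. The share of ribosomal protein mRNAs was 20.5% in control, 17.9% with SAHA, 24.0% with sonidegib and 22.9% with the combination.

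**Figure D1:**
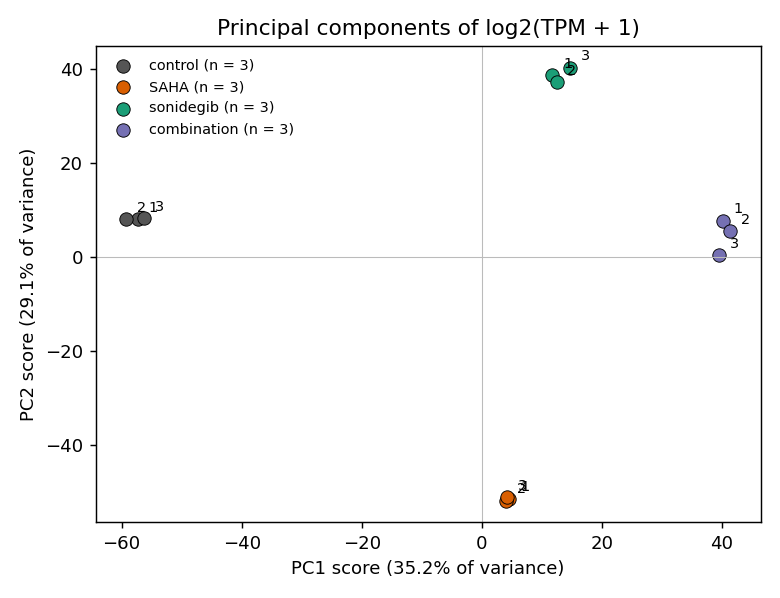
First and second principal component scores (no unit) of log2(TPM + 1) for the 12 libraries, coloured by group and numbered by replicate. Component 1 (35.2% of variance) sets control apart from the other groups, and component 2 (29.1%) sets SAHA and sonidegib at opposite ends.

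The comparison of SAHA with control compared cells given SAHA for 12 h with control cells. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, GRCh38), which encodes the cyclin-dependent kinase inhibitor p21, had the largest rise, from 4.38 ± 0.832 to 113 ± 2.51 TPM (log2 change 4.42 ± 0.10, adjusted p = 1.51e-10). MYC, a growth-promoting transcription factor, fell from 92.7 ± 11.2 to 37.4 ± 3 TPM (-1.28 ± 0.091, adjusted p = 3.48e-07). TYMS, the thymidylate synthase that supplies DNA replication, fell from 124 ± 13.4 to 22.3 ± 2.97 TPM (-2.42 ± 0.092, adjusted p = 3.5e-09). Among the other large rises were the actin-binding coronin CORO1A (ENSG00000102879, chromosome 16, 30182827 to 30189076, 4.03 ± 0.13), the actin-bundling fascin FSCN1 (3.66 ± 0.083), the JNK scaffold MAPK8IP1 (3.92 ± 0.10) and the guanosine monophosphate reductase GMPR (3.81 ± 0.10). Large rises were also assigned to the beta-tubulins TUBB2B (3.66 ± 0.12) and TUBB4A (3.65 ± 0.13) and to ACTBL2 (3.71 ± 0.15), whose sequences closely resemble other tubulins and actins, so that reads can be shared between them. The largest falls were in OLFM4, a secreted glycoprotein (-3.25 ± 0.10), ADI1, an enzyme of methionine salvage (-3.21 ± 0.067), and MMP7, a secreted metalloprotease (-3.18 ± 0.14). LY6D (-3.14 ± 0.10), NEURL3 (-3.12 ± 0.089), GLYATL2 (-2.92 ± 0.12) and LANCL2 (-2.88 ± 0.060) followed. ALPP, an alkaline phosphatase with near-identical relatives, was also lower (-3.00 ± 0.29).

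Genes of DNA replication and division fell together. In the S phase and replication list 27 of 29 genes fell and none rose (camera adjusted p = 5.64e-11, or adjusted p = 0.247 with an estimated correlation), with UHRF1, which helps to maintain DNA methylation, at -1.99 on the log2 scale. For all lists set beforehand, the p with an estimated correlation was also adjusted over the lists. In the G2/M and mitosis list 28 of 30 fell (adjusted p = 1.29e-09, or p = 0.322 with an estimated correlation), among them the proliferation marker MKI67 (-1.43). Of the homologous recombination and crosslink repair genes 13 of 18 fell (adjusted p = 0.000994, or p = 0.247 with an estimated correlation), for example RAD51D (-1.49). Of the MYC and ribosome biogenesis genes 19 of 24 fell and 1 rose (adjusted p = 2.73e-06, or p = 0.214 with an estimated correlation), with NCL at -1.67, while ODC1, a direct MYC target, rose by 0.45. Of the CDK inhibitors and growth arrest genes 10 of 14 rose and 1 fell (adjusted p = 0.00404, or p = 0.434 with an estimated correlation), including CDKN2D (2.56 ± 0.084).

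Metabolic and stress programmes moved in both directions. Cholesterol synthesis and uptake genes rose in 18 of 23 cases and fell in 1 (adjusted p = 7.64e-05, or p = 0.322 with an estimated correlation), with HMGCS1 at 1.51. Fatty acid synthesis genes rose in 8 of 11 (adjusted p = 0.0144, or p = 0.244 with an estimated correlation), among them LPIN1 (1.5). Lysosome and autophagy genes rose in 20 of 24 and fell in 3 (adjusted p = 7.57e-05, or p = 0.291 with an estimated correlation), with WIPI1 at 1.97 and MAP1LC3B at 1.63. NRF2 targets, which respond to oxidative stress, rose in 11 of 15 and fell in 1 (adjusted p = 0.00346, or p = 0.214 with an estimated correlation), for example OSGIN1 (1.47) and SRXN1 (1.36). Amino acid response genes, targets of ATF4, fell in 12 of 21 and rose in 2 (adjusted p = 0.00442, or p = 0.322 with an estimated correlation), with TRIB3 at -2.01, ATF5 at -2.50 and, in the opposite direction, ATF3 at 1.29. Nuclear-encoded oxidative phosphorylation genes fell in 14 of 24 and rose in 3 (adjusted p = 0.0144, or p = 0.47 with an estimated correlation), and ribosomal protein genes fell in 17 of 32 (adjusted p = 0.00404, or p = 0.62 with an estimated correlation). All 13 mitochondrially encoded mRNAs rose (adjusted p = 0.00956, or p = 0.62 with an estimated correlation), MT-CO1 by 0.68, beside a mitochondrial ribosomal RNA share that went from 0.616% to 1.24%. The stress chaperone HSPA1A rose by 2.33 ± 0.053, although its neighbour HSPA1B is nearly identical in sequence, and HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.32 ± 0.082.

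Neuronal genes rose in 6 of 8 and fell in 1 (adjusted p = 0.0347, or p = 0.256 with an estimated correlation), with MAPT at 2.79 and TUBB3 at 2.70 ± 0.070. Interferon-stimulated genes rose in 14 of 20 and fell in 2 (adjusted p = 0.00509, or p = 0.47 with an estimated correlation), for example IFIT1 (1.58). Hypoxia genes rose in 10 of 16 and fell in 2 (adjusted p = 0.0499, or p = 0.62 with an estimated correlation), a call lost in 9 of 18 alternatives. The EGFR ligand AREG rose from 1.54 ± 0.617 to 20.6 ± 1.3 TPM (3.11 ± 0.22), the matricellular gene CCN2 by 3.29 ± 0.12 and the basal keratin KRT17 by 2.20 ± 0.090, and the luminal factor SPDEF fell by 2.53. EGFR itself stood at 623 ± 57.3 TPM in control and 569 ± 46.7 TPM with SAHA (adjusted p = 0.208). It passed the test, lower with SAHA, after median-of-ratios and 75th percentile scaling (-0.201 and -0.195). Of the drug's own targets, HDAC1 rose by 0.77 ± 0.065 and HDAC3 by 0.96 ± 0.069, HDAC6 rose by 0.66 ± 0.13, HDAC2 changed by -0.68 ± 0.10, and 6 of the 11 zinc-dependent deacetylases rose and 3 fell (camera adjusted p = 0.273, list not called). KAT2A, a histone acetyltransferase, changed by -1.74 ± 0.084. Among genes often used as references, ACTB rose by 0.32 ± 0.077, a call lost after median-of-ratios scaling, and GAPDH changed by -0.50 ± 0.074. The pro-apoptotic gene BCL2L11 (BIM) rose from 12.3 ± 0.658 to 23.4 ± 1.74 TPM (0.87 ± 0.083).

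The remaining lists were not called for SAHA by camera. They had the following numbers higher and lower: histone acetyltransferases 3 and 8 of 12, pro-apoptotic genes 8 and 4 of 20, anti-apoptotic genes 3 and 3 of 11, endoplasmic reticulum chaperones 12 and 2 of 18, cytosolic heat shock proteins 7 and 3 of 14, and glycolysis 5 and 8 of 17. For class I antigen presentation they were 7 and 4 of 14, for NF-kB and inflammatory cytokines 2 and 6 of 14, for EGFR and MAPK signalling 12 and 3 of 22, for the Wnt pathway 7 and 4 of 14, for the Notch pathway 6 and 5 of 12, and for TGF-beta targets 5 and 1 of 13. Epithelial genes had 6 and 7 of 19, mesenchymal genes 4 and 4 of 11, basal epithelial genes 8 and 5 of 15, luminal epithelial genes 2 and 5 of 9, stem cell genes 4 and 4 of 12, drug efflux transporters 5 and 0 of 7, and replication-independent histones 5 and 5 of 13. Markers of other cell types had few expressed members: leukocyte markers 3 and 0 of 5, fibroblast and endothelial markers 2 and 2 of 5, and erythroid and hepatic markers no gene that reached the mean of 1 TPM. Metallothioneins had 3 higher and 0 lower of 4, too few for the list test, with MT1X at 1.18 ± 0.056. Among these lists the majority turned for the Notch pathway under quantile normalization (5 higher and 6 lower) and for epithelial genes without mitochondrial genes (8 and 7).

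In all, 8176 genes changed with SAHA, 4430 higher and 3746 lower, and 1213 of the rises and 800 of the falls were at least 2-fold. Falls outnumbered rises under other scalings, with 4094 higher and 4309 lower after median-of-ratios, 4143 and 4263 after 75th percentile and 4093 and 4270 after quantile scaling. Camera called 9 lists higher and 7 lower of 39, and none of them with an estimated correlation between the genes. Calls were also lost for lists whose estimated correlation lay under the preset 0.01, among them NRF2 targets (-0.0528) and fatty acid synthesis (-0.00494). A higher correlation within these lists themselves cannot account for their lost calls. The adjustment runs over all lists, so correlation within other lists can contribute, and the cause was not tested. Counts adjusted over the list alone differed from those over all genes only for 1 more lower gene in the G2/M and mitosis, homologous recombination, oxidative phosphorylation, glycolysis and Hedgehog lists and 1 more higher gene in the epithelial and luminal lists.

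**Figure D2:**
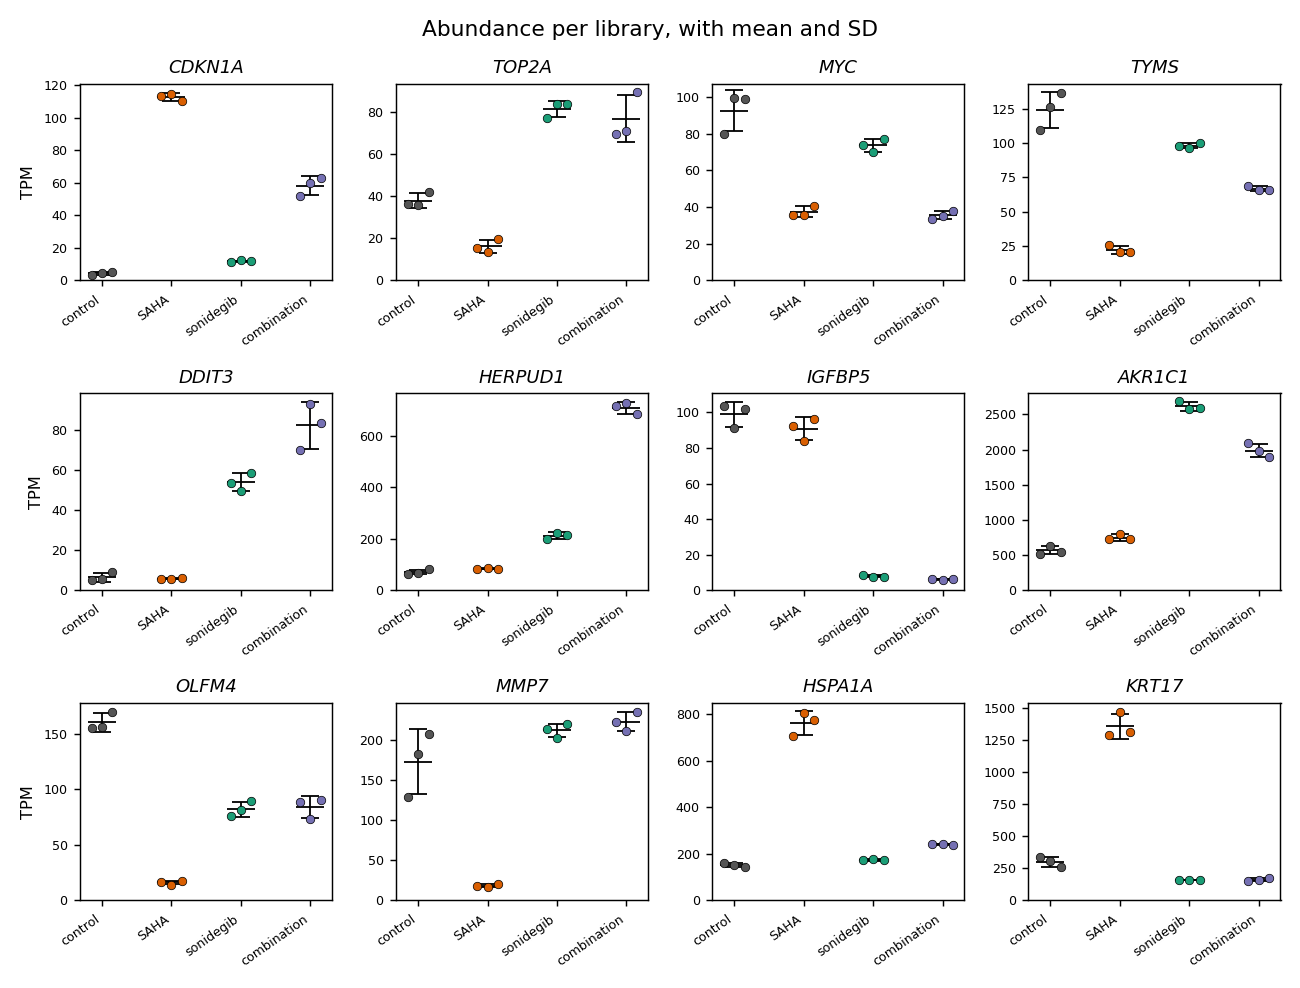
TPM per library (linear axes from 0) of 12 genes in the 4 groups, with points for the 3 libraries and a black bar with whiskers for mean and SD. CDKN1A went from 4.38 ± 0.832 TPM in control to 113 ± 2.51 with SAHA and 58.3 ± 5.89 with the combination, and IGFBP5 from 98.9 ± 6.82 to 7.84 ± 0.519 with sonidegib.

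Sonidegib against control compared cells given sonidegib for 72 h with control cells. DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), the stress transcription factor CHOP, rose from 6.48 ± 2.15 to 53.8 ± 4.58 TPM (2.91 ± 0.17, adjusted p = 1.13e-07). The aldo-keto reductases AKR1C3 (ENSG00000196139, chromosome 10, 5035354 to 5107686) and AKR1C1 (ENSG00000187134, chromosome 10, 4963253 to 4983283) rose to 249 ± 3.37 and 2616 ± 62.8 TPM (2.79 ± 0.057 and 2.21 ± 0.068), though they are close relatives that can share reads. IGFBP5, which binds insulin-like growth factors, fell from 98.9 ± 6.82 to 7.84 ± 0.519 TPM (-3.50 ± 0.079, adjusted p = 4.45e-10). Other large rises were in ICAM5 (2.72 ± 0.11), the D-lactate dehydrogenase LDHD (2.54 ± 0.11), the calpain CAPN5 (2.36 ± 0.090) and the microtubule linker CLIP2 (2.29 ± 0.066). Other large falls were in the amino acid transporter SLC6A14 (-2.99 ± 0.35), the neuropeptide galanin GAL (-2.99 ± 0.18), the protease inhibitor TFPI2 (-2.86 ± 0.12), ATF5 (-3.16 ± 0.16) and IGSF23 (-3.78 ± 0.24), and reads assigned to ALPP also fell (-4.10 ± 0.29).

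Hedgehog transcripts were scarce in these cells. PTCH1, a receptor and transcriptional target of the pathway, rose from 2.47 ± 0.313 to 4.3 ± 0.738 TPM (0.60 ± 0.14, adjusted p = 0.00313). Of 10 tested Hedgehog genes 5 rose and 0 fell, the list was not called (camera adjusted p = 0.237), and SAHA alone gave 6 higher and 1 lower (camera adjusted p = 0.273). The pathway's transcription factor GLI1 and SMO lay below the expression filter. Tested without it, GLI1 had log2 changes of 0.55 ± 0.19 with sonidegib (adjusted p = 0.0622), 1.3 ± 0.19 with SAHA (adjusted p = 0.000449) and 1.13 ± 0.19 with the combination (adjusted p = 0.00104). SMO had changes of -0.26 with sonidegib (adjusted p = 0.0817), -0.41 with SAHA (adjusted p = 0.00897) and -0.78 with the combination (adjusted p = 0.000131). The efflux pump ABCB1, also below the filter, had changes of 1.21 with SAHA (adjusted p = 8.83e-05) and -1.05 in the combination against SAHA (adjusted p = 0.000359). GLI2, HHIP, the ligand SHH and the efflux pump ABCG2 passed the test in no comparison without the filter.

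The amino acid response and the NRF2 programme rose and the MYC programme fell. Of the ATF4 targets 17 of 21 rose and 3 fell (adjusted p = 0.000516, or p = 0.353 with an estimated correlation), with ATF3 at 2.03 beside DDIT3. ATF5, named above among the large falls, belongs to the same list. NRF2 targets rose in 12 of 15, AKR1C1 among them, and fell in 1 (adjusted p = 0.000127, or p = 0.0637 with an estimated correlation). MYC and ribosome biogenesis genes fell in 21 of 24 and rose in 0 (adjusted p = 1.91e-08, or p = 0.0827 with an estimated correlation), with ODC1, which makes polyamines, from 65.2 ± 4.88 to 12.9 ± 1.57 TPM (-2.25 ± 0.10), the spermidine synthase SRM at -1.96 and MYC itself at -0.32 ± 0.091 (adjusted p = 0.0111). The MYC call was lost under quantile normalization, at -0.145. CDK inhibitors and growth arrest genes rose in 13 of 14 and fell in 1 (adjusted p = 3.95e-05, or p = 0.404 with an estimated correlation), with GADD45A at 1.97, CDKN1C at 1.77 and CDKN1A at 1.27. S phase genes fell in 23 of 29 and rose in 2 (adjusted p = 2.54e-06, or p = 0.526 with an estimated correlation), with UHRF1 at -1.67, MCM5 at -1.68 and TK1, in the other direction, at 1.05. G2/M genes rose in 17 of 30 and fell in 1 (adjusted p = 0.00119, or p = 0.644 with an estimated correlation), TOP2A from 37.9 ± 3.44 to 81.4 ± 3.79 TPM (1.09 ± 0.13), while MKI67 fell by 0.47.

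Further lists were also called. Lysosome and autophagy genes rose in 15 of 24 and fell in 3 (adjusted p = 0.00814, or p = 0.644 with an estimated correlation). Notch genes rose in 7 of 12 and fell in 2 (adjusted p = 0.0471, or p = 0.644 with an estimated correlation), with the ligands JAG1 at 1.18 and JAG2 at 1.40. The Notch call was lost in 8 of 18 alternatives. Mesenchymal genes rose in 7 of 11 and fell in 1 (adjusted p = 0.0131, or p = 0.309 with an estimated correlation), with SNAI1 at 1.33. Ribosomal protein genes rose in 19 of 32 and fell in none (adjusted p = 0.00101, or p = 0.644 with an estimated correlation), RPL3 by 0.50. Mitochondrially encoded mRNAs moved apart: 5 of 13 rose, most of all MT-ND6 (1.11 ± 0.12) and MT-ND4 (0.88 ± 0.11), and 7 fell, most of all MT-CYB (-1.62 ± 0.10) and MT-ND2 (-1.39 ± 0.10), so the list was not called (camera adjusted p = 0.775). The mitochondrial ribosomal RNA share was 2.22% here against 0.616% in control, and many nuclear copies of mitochondrial genes make read assignment uncertain. SREBF1, a driver of lipid synthesis, fell from 81.2 ± 5.91 to 24.7 ± 2.71 TPM (-1.68 ± 0.15), the chemokines CXCL1 and CXCL8 changed by -2.37 and -2.25, and HDAC2 by -0.74 ± 0.10. HDAC1 (-0.07 ± 0.065, adjusted p = 0.398) and BCL2L11 (0.00 ± 0.083, adjusted p = 0.978) did not pass the test. Under quantile normalization HDAC1 turned to 0.15 with an adjusted p of 0.025, the lowest of a range up to 0.942 over the alternatives.

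**Figure D3:**
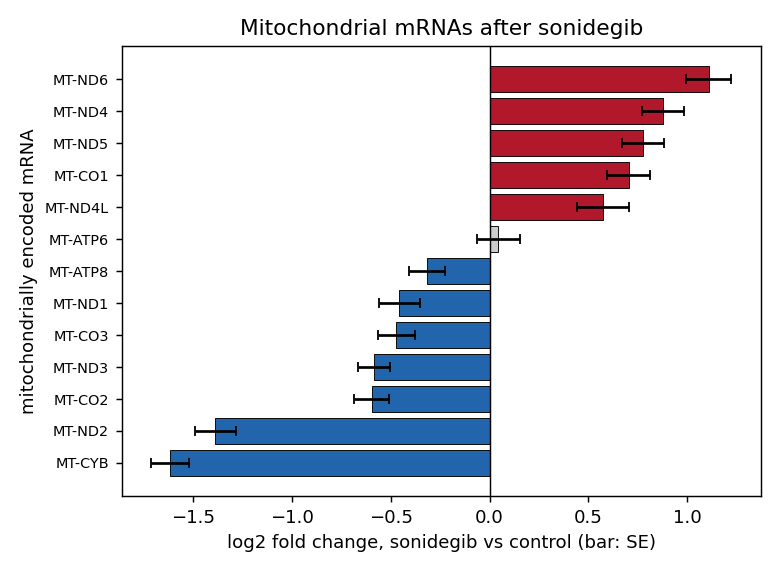
Log2 fold change of TPM + 1 (bars, with SE) for the 13 mitochondrially encoded mRNAs, sonidegib against control, in red and blue where the adjusted p was under 0.05 and grey otherwise. The changes ranged from -1.62 for MT-CYB to 1.11 for MT-ND6.

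With sonidegib 7712 genes changed, 3641 higher and 4071 lower, and 752 of the rises and 707 of the falls were at least 2-fold. Rises outnumbered falls after 75th percentile scaling (4205 and 3806) and without control replicate 3 (3639 and 3529). Camera called 8 lists higher and 2 lower of 39, and none with an estimated correlation. Adjusted over the list alone, 25 S phase genes were lower, 9 mesenchymal genes higher and 2 NRF2 targets lower.

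The combination against control asked what the treatments did together. IGFBP5 (-3.82 ± 0.079), the potassium channel KCNN4 (ENSG00000104783, chromosome 19, 43766533 to 43781261, -3.68 ± 0.057, from 323 ± 7.24 to 24.2 ± 0.657 TPM, adjusted p = 1.48e-11), LANCL2 (-3.53 ± 0.060), the protein kinase A subunit PRKAR1B (-3.56 ± 0.15), ATF5 (-3.52 ± 0.16) and IGSF23 (-4.04 ± 0.24) were among the largest falls, as was ALPP (-5.68 ± 0.29). FSCN1 (ENSG00000075618, chromosome 7, 5592823 to 5606655) rose from 2.17 ± 0.189 to 35.7 ± 2.2 TPM (3.53 ± 0.083, adjusted p = 1.1e-10). DDIT3 reached 82.1 ± 11.5 TPM (3.50 ± 0.17), and HERPUD1 (ENSG00000051108, chromosome 16, 56932048 to 56944863), a component of the machinery that degrades misfolded proteins of the endoplasmic reticulum, rose from 71 ± 9.05 to 708 ± 22.4 TPM (3.31 ± 0.079, adjusted p = 1.11e-10). CDKN1A (3.47 ± 0.10), CAPN5 (3.21 ± 0.090), AZIN2 (3.12 ± 0.13), RAP1GAP (3.09 ± 0.093) and LDHD (3.06 ± 0.11) made up the rest of the largest rises. PTCH1 rose by 0.93 ± 0.14 and BCL2L11 by 0.99 ± 0.083, and MYC fell to 35.6 ± 2.1 TPM (-1.35 ± 0.091).

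By list, MYC and ribosome biogenesis genes fell in 23 of 24 (adjusted p = 2.79e-08, or p = 0.146 with an estimated correlation), with DKC1 at -2.29 and ODC1 at -2.44. S phase genes fell in 21 of 29 and rose in 1 (adjusted p = 6.7e-05, or p = 0.653 with an estimated correlation), whereas G2/M genes had 9 higher and 6 lower of 30 and were not called (camera adjusted p = 0.58), CDK1 at 1.03 and PLK1 at -0.68. CDK inhibitors and growth arrest genes rose in 11 of 14, GADD45A by 2.94 ± 0.12, and fell in 1 (adjusted p = 0.000213, or p = 0.465 with an estimated correlation). NRF2 targets rose in 11 of 15 and fell in 2 (adjusted p = 0.00683, or p = 0.146 with an estimated correlation). Lysosome and autophagy genes rose in 19 of 24 and fell in 1 (adjusted p = 7.27e-05, or p = 0.385 with an estimated correlation). Epithelial genes fell in 14 of 19 and rose in 3 (adjusted p = 0.00957, or p = 0.152 with an estimated correlation), and luminal epithelial genes fell in 8 of 9 and rose in 1 (adjusted p = 0.0181, or p = 0.152 with an estimated correlation), with FOXA1 at -2.39. Ribosomal protein genes rose in 16 of 32 and fell in 1 (adjusted p = 0.0383, or p = 0.888 with an estimated correlation), a call lost in 5 of 18 alternatives. In this comparison 8883 genes changed, 4140 higher and 4743 lower, with 1089 rises and 1444 falls of at least 2-fold. Rises outnumbered falls after median-of-ratios (4594 and 4554), 75th percentile (4769 and 4398) and quantile scaling (4666 and 4472) and without mitochondrial genes (4557 and 4382). Camera called 4 lists higher and 4 lower, none with an estimated correlation. Adjusted over the list alone, 22 S phase genes and 3 NRF2 targets were lower.

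The combination against SAHA asked what sonidegib pretreatment changed in SAHA-treated cells. MMP7 (ENSG00000137673, chromosome 11, 102520508 to 102530753) stood at 223 ± 11.8 TPM against 17.9 ± 1.87 TPM with SAHA alone (3.57 ± 0.14, adjusted p = 1.65e-08), near its control level of 174 ± 40.3 TPM. OLFM4 (ENSG00000102837, chromosome 13, 53028759 to 53052057) stood at 84.1 ± 9.82 against 15.9 ± 1.69 TPM (2.33 ± 0.10, adjusted p = 2.77e-08). DDIT3 (3.62 ± 0.17), HERPUD1 (3.06 ± 0.079) and TMEM203 (2.30 ± 0.28) were the other largest rises. The carboxypeptidase gene CPA4 (ENSG00000128510, chromosome 7, 130293134 to 130324180) was the largest fall (-4.59 ± 0.20), at 2.32 ± 1.02 against 76.3 ± 0.976 TPM, and TFPI2 (-3.71 ± 0.12), IGFBP5 (-3.70 ± 0.079) and ACTBL2 (-3.81 ± 0.15) were also among the largest falls. CDKN1A was lower than with SAHA alone (-0.95 ± 0.10, adjusted p = 1.99e-05), while MYC (-0.07 ± 0.091, adjusted p = 0.566) and BCL2L11 (0.13 ± 0.083, adjusted p = 0.22) did not pass the test. BCL2L11 passed it under all 3 other scalings, at 0.246 (median-of-ratios), 0.265 (75th percentile) and 0.252 (quantile).

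G2/M and mitosis genes were higher in 28 of 30 and lower in none (adjusted p = 8.58e-17, or p = 0.23 with an estimated correlation), TOP2A by 2.19 ± 0.13. S phase genes went both ways, 10 higher and 6 lower of 29, and were called higher (adjusted p = 0.0266, or p = 0.52 with an estimated correlation), with TYMS at 1.55 ± 0.092. Recombination and crosslink repair genes were higher in 9 of 18 (adjusted p = 0.00183, or p = 0.23 with an estimated correlation). Ribosomal protein genes were higher in 29 of 32 (adjusted p = 2.77e-10, or p = 0.324 with an estimated correlation), RPL11 by 0.59, and ATF4 targets in 15 of 21, with 2 lower (adjusted p = 3.72e-05, or p = 0.23 with an estimated correlation). CDK inhibitor genes were higher in 7 of 14 and lower in 1 (adjusted p = 0.0254, or p = 0.484 with an estimated correlation), with GADD45A at 1.42. Notch genes were higher in 8 of 12 and lower in 2 (adjusted p = 0.0041, or p = 0.43 with an estimated correlation), with NOTCH3 at 0.92. Oxidative phosphorylation genes were higher in 9 of 24, with 4 lower (adjusted p = 0.0308, or p = 0.484 with an estimated correlation).

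Lower in the combination were cytosolic heat shock genes, 13 of 14 (adjusted p = 0.000179, or p = 0.23 with an estimated correlation), with HSPA1A at -1.66. Epithelial genes were lower in 14 of 19 and higher in 1 (adjusted p = 0.0037, or p = 0.171 with an estimated correlation), with the keratins KRT18 at -1.27 and KRT19 at -1.26. Fatty acid synthesis genes were lower in 9 of 11 (adjusted p = 0.00442, or p = 0.171 with an estimated correlation), with SREBF1 at -2.39, and cholesterol genes in 13 of 23, with 4 higher (adjusted p = 0.0452, or p = 0.52 with an estimated correlation). MYC and ribosome biogenesis genes were lower in 17 of 24 (adjusted p = 0.0041, or p = 0.324 with an estimated correlation), although NPM1 was higher by 0.82. Glycolysis genes were lower in 12 of 17 and higher in 2 (adjusted p = 0.0287, or p = 0.324 with an estimated correlation). Hypoxia genes were lower in 11 of 16 and higher in 1 (adjusted p = 0.022, or p = 0.52 with an estimated correlation). Interferon-stimulated genes were lower in 12 of 20 and higher in 1 (adjusted p = 0.0299, or p = 0.52 with an estimated correlation). EGFR and MAPK genes were lower in 15 of 22 and higher in 3 (adjusted p = 0.0308, or p = 0.52 with an estimated correlation), with DUSP5 at -1.42. TGF-beta targets were lower in 7 of 13 (adjusted p = 0.0308, or p = 0.43 with an estimated correlation), with CCN2 at -2.32, and neuronal genes in 6 of 8 (adjusted p = 0.0482, or p = 0.304 with an estimated correlation). At a mean of at least 5 TPM the glycolysis, hypoxia, cholesterol, and EGFR and MAPK calls were lost. The neuronal call was lost in 9 of 17 alternatives and the cholesterol call in 7 of 18.

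In this comparison 7100 genes differed, 2506 higher and 4594 lower, with 349 rises and 706 falls of at least 2-fold. The split depends on the scaling, because the median change of all genes was -0.12 as deposited and -0.00897 after median-of-ratios scaling, which gave 3502 higher and 3735 lower. After 75th percentile scaling 3641 were higher and 3608 lower, and after quantile normalization 3708 and 3686. Camera called 8 lists higher and 11 lower, none with an estimated correlation. Adjusted over the list alone, 11 S phase genes were higher and 9 lower, 14 cholesterol genes and 7 neuronal genes were lower, and 2 hypoxia genes were higher.

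The combination against sonidegib gave the SAHA response of pretreated cells. CDKN1A (2.20 ± 0.10, adjusted p = 1.37e-07) and CORO1A (2.60 ± 0.13) again rose, as did ROPN1L (0.83 ± 0.0346 to 10.9 ± 2.1 TPM, 2.69 ± 0.14), the Wnt modulator DACT3 (2.57 ± 0.11) and the growth factor BMP6 (2.27 ± 0.12). TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559), a pseudokinase induced by ATF4, fell from 113 ± 4.78 to 23.9 ± 0.648 TPM (-2.19 ± 0.051, adjusted p = 1.42e-09). The macrophage growth factor CSF1 (-2.37 ± 0.12), the phosphate transporter SLC34A2 (-2.32 ± 0.094), the netrin NTN4 (-2.22 ± 0.14) and CDHR2 (-2.88 ± 0.57) also fell. HERPUD1 (1.73 ± 0.079) and BCL2L11 (0.99 ± 0.083) rose and MYC fell (-1.03 ± 0.091).

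Cholesterol synthesis and uptake genes rose in 16 of 23 and fell in 2 (adjusted p = 0.000169, or p = 0.502 with an estimated correlation), INSIG1 by 1.43. ATF4 targets fell in 13 of 21 and rose in 3 (adjusted p = 0.00865, or p = 0.502 with an estimated correlation). Endoplasmic reticulum chaperones rose in 8 of 18, HSPA5 by 1.37, and fell in 1 (adjusted p = 0.0233, or p = 0.856 with an estimated correlation). Lysosome genes rose in 13 of 24 and fell in 2 (adjusted p = 0.0233, or p = 0.856 with an estimated correlation). Neuronal genes rose in 5 of 8 and fell in 1 (adjusted p = 0.0233, or p = 0.439 with an estimated correlation). Mitochondrially encoded mRNAs rose in 9 of 13 with none lower (adjusted p = 0.00865, or p = 0.856 with an estimated correlation), beside a mitochondrial ribosomal RNA share of 2.61% against 2.22%. G2/M genes fell in 13 of 30 and rose in 2 (adjusted p = 0.0274, or p = 0.86 with an estimated correlation). The test called 5370 genes, 2442 higher and 2928 lower, with 188 rises and 315 falls of at least 2-fold. Rises outnumbered falls after quantile normalization (3091 and 2917), without mitochondrial genes (2785 and 2717) and without combination replicate 1 (2501 and 2438). Camera called 5 lists higher and 2 lower, none with an estimated correlation, and the 2 lower lists became 1 without combination replicate 1 or 2 and 5 without SAHA replicate 2 or sonidegib replicate 3. Adjusted over the list alone, 3 cholesterol genes and 15 ATF4 targets were lower, 14 lysosome genes higher and 3 lower, 6 neuronal genes higher and 11 mitochondrial mRNAs higher.

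The interaction tested whether the SAHA response differed with sonidegib, as the change in the combination against sonidegib minus the change in SAHA against control. OLFM4 (3.29 ± 0.14, adjusted p = 1.9e-07) and MMP7 (3.25 ± 0.20, adjusted p = 1.24e-06), which SAHA alone lowered, did not fall on the sonidegib background. CDKN1A rose less there (-2.22 ± 0.15, adjusted p = 1.96e-06), and TYMS fell less (1.88 ± 0.13). HERPUD1 rose more (1.49 ± 0.11, adjusted p = 4.37e-06). GAL (3.17 ± 0.25), C1orf53 (3.0 ± 0.27) and ADI1 (2.68 ± 0.10, adjusted p = 1.4e-07) completed the largest positive differences, and ACTBL2 (-2.99 ± 0.22), GMPR (-2.85 ± 0.14), FAM220A (-2.71 ± 0.91, adjusted p = 0.0421), CDHR2 (-2.67 ± 0.81, adjusted p = 0.0275) and RAET1G (-2.64 ± 0.21) the largest negative ones. The FAM220A call was lost in 14 of 24 alternatives (values from -3.61 to -1.52) and the CDHR2 call in 8 of 23 (-5.01 to -1.07).

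Of the 7 lists that SAHA alone lowered, 6 had positive interactions, and the amino acid response list was not called (camera adjusted p = 0.691). The interaction subtracts the SAHA change of the same libraries, which favours positive values in lists picked for a fall. S phase genes were positive in 28 of 29 (adjusted p = 3.73e-19, or p = 0.106 with an estimated correlation), G2/M genes in 23 of 30 (adjusted p = 9.89e-11, or p = 0.284 with an estimated correlation), with MKI67 at 1.25. Recombination and crosslink repair genes were positive in 5 of 18 (adjusted p = 0.000263, or p = 0.241 with an estimated correlation). MYC and ribosome biogenesis genes were positive in 12 of 24 and negative in 1 (adjusted p = 4.65e-07, or p = 0.106 with an estimated correlation), with NCL at 1.17. Oxidative phosphorylation genes were positive in 12 of 24 and negative in 2 (adjusted p = 0.000191, or p = 0.284 with an estimated correlation). Ribosomal protein genes were positive in 8 of 32 (adjusted p = 0.00876, or p = 0.622 with an estimated correlation), and replication-independent histones in 5 of 13 with 1 negative (adjusted p = 0.0392, or p = 0.416 with an estimated correlation).

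Negative interactions were found for NRF2 targets in 13 of 15 genes, with 1 positive (adjusted p = 1.05e-05, or p = 0.0317 with an estimated correlation). This was the one list call that passed with an estimated correlation, with OSGIN1 at -1.57. Against control the median change of NRF2 targets was 0.44 with SAHA, 0.73 with sonidegib and 0.60 with the combination. Subtracting the SAHA change favours negative values in lists that SAHA alone raised, NRF2 targets among them. Interferon-stimulated genes were negative in 15 of 20 (adjusted p = 1.06e-05, or p = 0.284 with an estimated correlation), with MX1 at -1.59, lysosome and autophagy genes in 15 of 24 (adjusted p = 0.000263, or p = 0.284 with an estimated correlation), with WIPI1 at -1.69. EGFR and MAPK genes were negative in 13 of 22 (adjusted p = 0.000263, or p = 0.315 with an estimated correlation), with DUSP5 at -2.13. CDK inhibitor genes were negative in 8 of 14 and positive in 1 (adjusted p = 0.00232, or p = 0.302 with an estimated correlation). Hypoxia genes were negative in 8 of 16 (adjusted p = 0.00983, or p = 0.492 with an estimated correlation). Zinc-dependent deacetylases were negative in 5 of 11 (adjusted p = 0.0307, or p = 0.294 with an estimated correlation), with HDAC1 at -0.56, and drug efflux transporters in 3 of 7 (adjusted p = 0.0136, or p = 0.302 with an estimated correlation). The leukocyte marker list, of which 5 genes were expressed, was negative in 4 (adjusted p = 0.00989, or p = 0.284 with an estimated correlation), with CORO1A at -1.43 and CD68 at -1.33. HSPA1A (-1.85) and the keratin KRT17 (-2.18) were also negative.

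**Figure D4:**
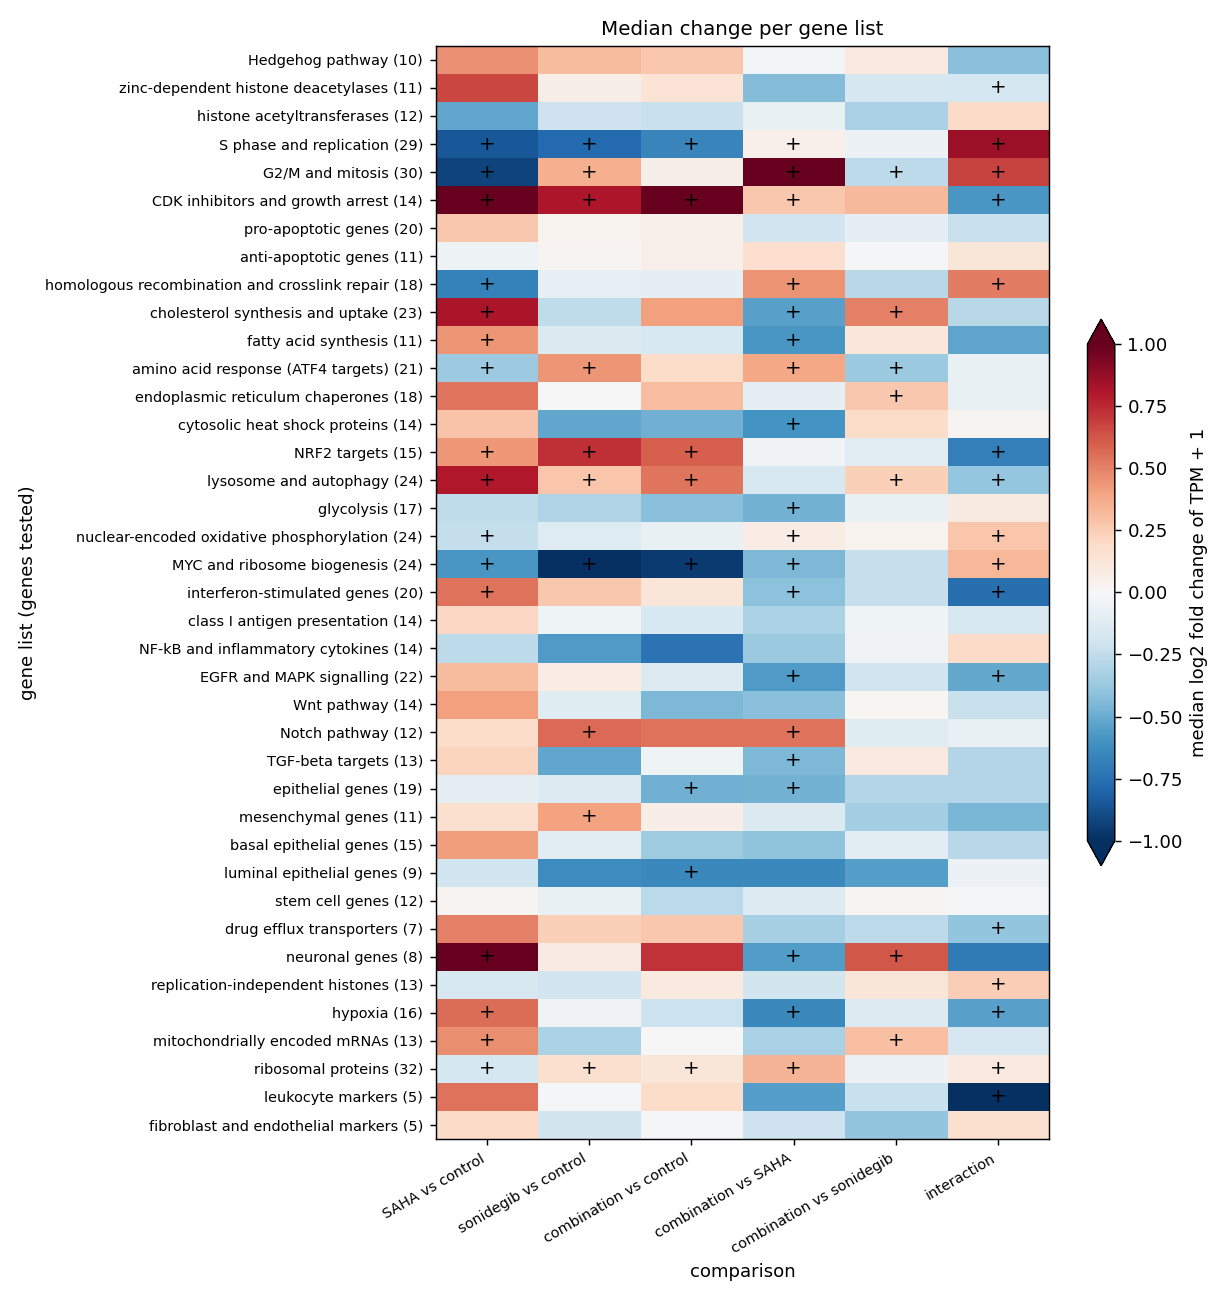
Median log2 fold change of TPM + 1 per gene list (vertical, with the number of genes tested) and comparison (horizontal), colours limited to -1 to 1, with a plus where the camera adjusted p with the preset correlation was under 0.05. The S phase list runs from -0.85 in SAHA against control to 0.86 in the interaction.

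In the interaction 4381 genes passed the test, 1642 positive and 2739 negative, 228 and 721 of them by at least 1 on the log2 scale. Median-of-ratios scaling gave 2392 positive and 2395 negative genes, quantile normalization 2373 and 2345, and the median over all genes, -0.07 as deposited, was 0.025 after quantile normalization. Camera called 7 lists positive and 9 negative. Adjusted over the list alone, 29 S phase, 26 G2/M, 16 MYC and 13 oxidative phosphorylation genes were positive, 4 repair and 6 ribosomal protein genes were positive, 10 CDK inhibitor and 15 EGFR and MAPK genes were negative, and hypoxia had 1 positive and 9 negative.

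Across all 13937 genes, the changes with SAHA in cells with and without sonidegib came from separate libraries and correlated with Pearson r = 0.546 and Spearman rho = 0.587 (genes are not independent replicates). Their fitted slope was 0.512 with a leave-one-out jackknife SE of 0.0676, where equal responses would give 1. Of the 8176 genes changed by SAHA alone, 81.0% kept their sign with sonidegib, 1922 rose and 1928 fell in both (776 and 787 for independent calls), and 355 moved in opposite directions (1587 for independent calls). Of these 8176 genes 3823 had a called interaction, 3703 of them against the SAHA change and 120 along it, although picking genes by the SAHA change favours the former. The differences between libraries with and without sonidegib, in cells without and with SAHA, correlated with Pearson r = 0.544 and Spearman rho = 0.541, at a slope of 0.805 with an SE of 0.11. A difference in preparation or processing shared by the libraries with sonidegib would also give such a correlation. Of 7712 genes changed by sonidegib alone 78.2% kept their sign, 1570 rose and 2678 fell in both (655 and 1342 for independent calls), and 681 moved in opposite directions (1932 for independent calls).

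**Figure D5:**
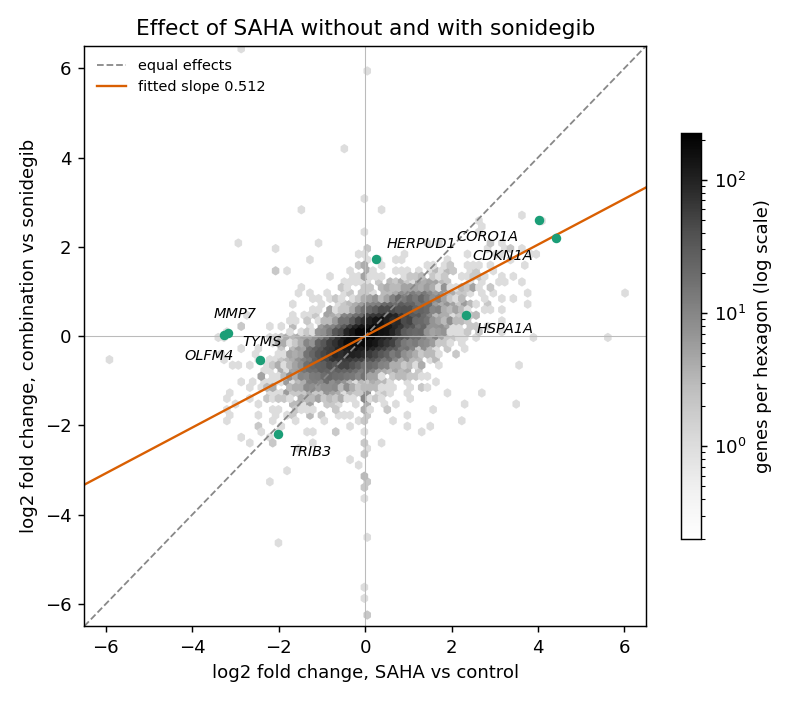
Log2 fold change of TPM + 1 with SAHA in cells without (horizontal) and with sonidegib (vertical) for 13937 genes, shaded by the number of genes per hexagon on a log scale, with the line of equal effects dashed and the fitted slope of 0.512 solid. CDKN1A lies at 4.42 and 2.20, and OLFM4 and MMP7 lie near 0 on the vertical axis.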

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

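The tests on all genes that sonidegib left unmoved, on a trend with mean expression, on named nuclear copies, on mRNAs with a copy inside AL669831.3, on RNAs without a poly(A) tail and on 5S ribosomal RNA were chosen only after the results were seen, as were the splicing factor and poly(A) lists themselves.

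Results listed here are differences of the SAHA response between cells with and without sonidegib that passed the interaction test. The test called 4381 genes, 1642 positive and 2739 negative. The named genes had log2 interactions of 3.29 (OLFM4), 3.25 (MMP7), 3.17 (GAL), 3.0 (C1orf53) and 2.68 (ADI1) on the positive side. On the negative side they were -2.99 (ACTBL2), -2.85 (GMPR), -2.71 (FAM220A), -2.67 (CDHR2) and -2.64 (RAET1G). Of the 16 lists called for the interaction 1, NRF2 targets, kept its call with an estimated correlation (adjusted p = 0.0317), and in the other 15 the adjusted p was between 0.106 and 0.622. Lists with a positive interaction had medians of 0.86 (S phase), 0.68 (G2/M), 0.51 (recombination and crosslink repair), 0.33 (MYC and ribosome biogenesis), 0.28 (oxidative phosphorylation), 0.25 (replication-independent histones) and 0.096 (ribosomal proteins, 0.0247 without sonidegib replicate 3). Lists with a negative interaction had medians of -1.01 (leukocyte markers), -0.75 (interferon-stimulated genes), -0.68 (NRF2 targets), -0.58 (CDK inhibitors), -0.54 (hypoxia), -0.51 (EGFR and MAPK signalling), -0.40 (drug efflux transporters), -0.39 (lysosome and autophagy) and -0.18 (zinc-dependent deacetylases, -0.285 without SAHA replicate 3).

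Of 100 groupings of the 12 libraries, 1, the real one, gave as many genes for the interaction (4381, highest other 688). A grouping that mixes treatments widens the spread within groups, which by itself lowers the number of calls. The count therefore speaks against groups that do not differ at all, and not for the interaction itself. For lists 1 grouping gave as many (16, highest other 15), so another grouping called nearly as many and an arbitrary split was not excluded. Other groupings can keep part of the treatment differences, so lists called there need not be false. For comparisons of a pair of groups the 10 splits are too few for a share under 0.05. The real splits called 8176, 7712, 8883, 7100 and 5370 genes, in the order SAHA, sonidegib and combination against control, then combination against SAHA and against sonidegib, and the highest other splits called 1, 1, 1, 3 and 1, so 1 of 10 splits was as large in each. Lists called were 16 (highest other 12), 10 (9), 8 (8), 19 (13) and 7 (8), so that 1, 1, 3, 1 and 2 of 10 splits called as many. Every other split mixes the groups unevenly and so keeps part of their difference, which camera can still call. Lists called there need not be false, and these counts decide nothing about the real calls.

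The SAHA changes were smaller after sonidegib, with a slope of 0.512 over all genes. Removal of GC and length trends left a slope of 0.513 (SE 0.056), and genes with a mean of at least 20 TPM, where the pseudocount hardly compresses changes, gave 0.513 (SE 0.07), so neither explains the pattern as a whole. Among 3579 genes that sonidegib left unmoved, whether or not SAHA changed them, the slope was 0.642 (SE 0.083), which argues against changes already made by sonidegib as the whole cause, although they may contribute. The median ratio of the SAHA change with to without sonidegib decided nothing, since it depended on which change picked the genes: it was 0.5 (spread 0.033) for 1945 unmoved genes called without sonidegib (0.297 and 0.612 for genes that sonidegib moved the same and the other way), while in 1308 unmoved genes called with it the inverse ratio was 1.02 (spread 0.063). The part of a difference in preparation or processing in this pattern cannot be told apart from that of sonidegib, since 5S ribosomal RNA was listed at 0 in the 6 libraries without it and at 1488 TPM or more in the 6 with it. A weaker transcriptional response to SAHA in pretreated cells also stays open.

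The mitochondrially encoded mRNAs moved apart after sonidegib, 7 lower and 5 higher of 13, although all but MT-ND6, which the other strand encodes, share a precursor transcript. Reads counted on named nuclear copies do not account for the falls, since those copies gained at most 0.059% of the TPM lost. Of the mRNAs without a copy inside AL669831.3 (chromosome 1, 586071 to 827796, from 10910 to 22980 TPM), MT-CYB at -1.62 and MT-ND3 at -0.58 fell. Their median change of -1.1 (spread 0.1) decides nothing, since it was taken over mRNAs picked for having fallen. The others without such a copy, MT-ND6, MT-ND5, MT-ND4 and MT-ND4L, rose (1.11, 0.78, 0.88 and 0.57). The sum of each fallen gene and its copies changed by a median of -0.584 (spread 0.1), which leaves sharing with unnamed copies open, and 5 of the 7 mRNAs with a copy inside AL669831.3 fell, so transfer of their reads to it cannot be told apart from a change of these mRNAs. More RNA without a poly(A) tail stays open, since 27 such RNAs changed by a median of -1.34 (spread 0.8) but 5S ribosomal RNA, outside that list, appeared at 1488 TPM or more, as does a difference in library preparation or read processing between libraries with and without sonidegib. A change of mitochondrial RNA processing or stability was not tested.

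Splicing factor genes were lower after sonidegib, 71 of 88 lower and 4 higher (median -0.62, camera p = 4.12e-16, and p = 0.0562 with an estimated correlation, both unadjusted). The fall of the listed genes remained, with a median of -0.586 (spread 0.042) after removal of GC and length trends and -0.445 (spread 0.028) after removal of the trend with mean expression. Of 10000 random lists matched on mean expression 0 had a median as low (random median -0.15, lowest -0.43). Neither these medians, the camera test nor the random lists decide on a cause, since the genes were listed after some had been seen to fall. A difference in library preparation or read processing along sonidegib (5S ribosomal RNA at 1488 TPM or more against 0) and a joint response of these genes both stay open.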

How the results depend on the processing

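The tests on protein-coding genes alone and on the data without the 2 libraries richest in ribosomal and small nuclear RNA were chosen only after the data had been seen. Counts of changed genes stayed within 1.5 times the reported counts in all 465 recomputed values. Over the alternatives the total ranged from 6408 to 8787 for SAHA, 6109 to 8076 for sonidegib, 6799 to 9418 for the combination, 5696 to 8401 for the combination against SAHA, 4466 to 6485 for the combination against sonidegib, and 3269 to 5351 for the interaction. The lowest interaction count came without the 2 libraries richest in small RNA. These ranges leave out the removal of GC and length trends, tested on 13636 genes. It gave 8301 genes for sonidegib (7660 before removal) and 5246 for the interaction, where 3728 of the 4394 genes called before removal were shared. The correlation of SAHA effects with and without sonidegib was 0.471 and that of sonidegib effects with and without SAHA 0.498 at a pseudocount of 0.1. They were 0.582 and 0.572 at a pseudocount of 5, 0.514 and 0.518 without the filter, and 0.583 and 0.577 at a mean of at least 5 TPM. The SAHA correlation was 0.657 among protein-coding genes alone. Without each library in turn they ranged from 0.517 (without sonidegib replicate 2) to 0.552 and from 0.519 (without SAHA replicate 3) to 0.543. The cause was not tested. With an estimated correlation camera called 0 lists higher and 0 lower in each comparison against control and in the combination against each drug, and 0 higher and 1 lower for the interaction. Fry called 21 higher and 9 lower for SAHA, 13 and 15 for sonidegib, 12 and 14 for the combination, 8 and 23 against SAHA, 9 and 15 against sonidegib, and 7 and 22 for the interaction. Fry tests a list against no change and not against the other genes. At a mean of at least 5 TPM 6 lists were lower in the combination against SAHA, with fewer genes tested. Against sonidegib 1 (without combination replicate 1 or 2) to 5 (without SAHA replicate 2 or sonidegib replicate 3) were lower when a library was left out.

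Of the list results that passed the test, 1241 recomputed values kept direction and side of the threshold. Another 123 missed the threshold, 75 of these with the estimated correlation, and their direction was not counted separately. The adjusted p for hypoxia with SAHA was 0.0567 at a pseudocount of 0.1 and 0.0808 at a mean of at least 5 TPM. It was between 0.0502 and 0.0679 without control replicate 1 or 2, SAHA replicate 1 or 3, sonidegib replicate 3 or combination replicate 2 (range over all alternatives 0.00049 to 0.62). Notch with sonidegib missed the threshold without any of the SAHA libraries, sonidegib replicate 2 or combination replicate 1 and at a pseudocount of 0.1 (0.0506 to 0.0597, range 0.000291 to 0.644). Ribosomal proteins in the combination missed it without control replicate 3, combination replicate 1 or 2 (0.175, 0.104 and 0.118) and after median-of-ratios scaling (0.0702, range 0.00764 to 0.888), and for the interaction with fry (0.119) and without sonidegib replicate 3 (0.103, range 0.000426 to 0.622), where the median fell from 0.0965 to 0.0247. In the combination against SAHA, cholesterol synthesis missed it without any control library (0.0509 to 0.054), after median-of-ratios scaling (0.068) and at a mean of at least 5 TPM (0.138, range 2.54e-05 to 0.52). The latter also ended the calls for glycolysis (range 1.85e-06 to 0.324), hypoxia (0.000127 to 0.52), and EGFR and MAPK genes (0.000382 to 0.52), each at 0.0535. Neuronal genes missed it without control replicate 1 or 3, SAHA replicate 1 or 2, sonidegib replicate 2 or combination replicate 3 and at a pseudocount of 0.1 (0.0509 to 0.0728, range 3.29e-06 to 0.304), and oxidative phosphorylation without SAHA replicate 1 (0.0554, range 0.00593 to 0.484). In the combination against sonidegib, G2/M missed it without combination replicate 1 or 2 (0.052 and 0.0672, range 0.00481 to 0.86) and mitochondrially encoded mRNAs without combination replicate 1 (0.052, range 0.000153 to 0.856). Interaction lists that missed it were histones without control replicate 3 or combination replicate 1 (0.0625 and 0.061), at a pseudocount of 0.1 (0.0546) or a mean of at least 5 TPM (0.148, range 0.0162 to 0.416) and deacetylases without SAHA replicate 2 (0.0564, range 8.12e-05 to 0.294). Calls kept with medians moved over 1.5-fold were S phase against SAHA (0.0479 to 0.144 and 0.0175 without combination replicate 1 and 3, 0.169 after median-of-ratios scaling), chaperones against sonidegib (0.267 to 0.14 without combination replicate 3) and interaction deacetylases (-0.179 to -0.285 without SAHA replicate 3). Median-of-ratios scaling moved the latter to -0.0999, oxidative phosphorylation against SAHA to 0.2 and interaction ribosomal proteins to 0.188. At a mean of at least 5 TPM the deacetylases were at -0.37 and TGF-beta targets against SAHA at -0.747.

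Of the named gene values 4406 kept direction and side of the threshold, 24 kept direction alone, 5 passed it newly and 1 reversed. HDAC1 with sonidegib was 0.152 higher after quantile normalization (adjusted p = 0.025, range 0.025 to 0.942), and the cause was not tested. The FAM220A interaction missed the threshold in 14 of 24 alternatives (adjusted p from 0.0204 to 0.15), among them without control replicate 2 or 3, SAHA replicate 2 or 3, sonidegib replicate 1 or 3 and combination replicate 1 or 3. The CDHR2 interaction missed it in 8 of 23 (0.00849 to 0.0738), among them without SAHA replicate 1 or 3, sonidegib replicate 1 or 2 and combination replicate 2 or 3. After median-of-ratios scaling ACTB with SAHA rose by 0.244 (adjusted p = 0.0696, range 0.000881 to 0.0696). MYC with sonidegib changed by -0.145 after quantile normalization (adjusted p = 0.106, range 0.00125 to 0.106).

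Replicate numbers did not pair the libraries clearly. Residuals of libraries with the same number correlated between -0.0586 and 0.111, those with different numbers between -0.107 and 0.0966, and 6 of 12 libraries correlated best with one of their own number. With the number as a block 4562 genes were higher and 3879 lower with SAHA, and 1864 positive and 2934 negative for the interaction. The block left list values as they were but ended 4 calls: neuronal genes with SAHA (adjusted p = 0.0567, range 5.62e-08 to 0.256), Notch with sonidegib (0.0655), and cholesterol and neuronal genes in the combination against SAHA (both 0.0636). Spearman correlations of the change with GC content were -0.209 for the interaction, -0.166 in the combination against SAHA and -0.136 against sonidegib. No fit could separate sonidegib from the split in 5S ribosomal RNA, which follows it in all 12 libraries. TPM keep no record of depth, so its limit on low genes was not measured.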

Other observations

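The splicing factor and 5' terminal oligopyrimidine lists, the genes named from them and GAS5 were chosen after their values were seen. The prediction for the oligopyrimidine class was written before its test was run. Since the list was chosen after values had been seen, this was not a test set before the data. Camera p-values of these added lists were not adjusted.

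Splicing factor genes were lower in all 3 treated groups against control, comparisons that share the control libraries. With SAHA 63 of 88 were lower and 5 higher (median -0.47, camera p = 3.61e-12, and p = 0.0932 with an estimated correlation). RBMX, an RNA-binding protein of the spliceosome, changed by -2.36 ± 0.047 and HNRNPL by -1.40 ± 0.055. With sonidegib SFPQ changed by -2.41 ± 0.10, SRSF1 by -2.28 ± 0.15, and U2AF2, which recognises the end of introns, by -2.33 ± 0.072. EWSR1, an RNA-binding protein, went from 299 ± 13.7 TPM in control to 75 ± 5.77 TPM with sonidegib. With the combination 74 of 88 were lower and 5 higher (median -0.86, camera p = 9.4e-14, and p = 0.0754 with an estimated correlation), U2AF2 by -3.13 ± 0.072. The interaction was positive in 46 and negative in 3 (median 0.34, camera p = 3.96e-13, and p = 0.0819 with an estimated correlation).

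GAS5, a noncoding host gene of small nucleolar RNAs whose RNA is degraded when translated, rose with sonidegib (1.49 ± 0.072, adjusted p = 3.52e-08) and in the combination against SAHA (1.60 ± 0.072, adjusted p = 3.92e-08), and was lower with SAHA alone (-0.30 ± 0.072, adjusted p = 0.00373).

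Of 32 ribosomal protein mRNAs, which carry a 5' terminal oligopyrimidine tract, 19 rose with sonidegib and 13 did not pass the test (adjusted p = 0.00101, or p = 0.644 with an estimated correlation). A hypothesis was that the whole class rose. Of 28 other mRNAs with this tract 14 were higher and 7 lower, with a median of 0.167 (spread 0.064, camera p = 0.0441, and p = 0.417 with an estimated correlation), which left the hypothesis open. In the combination against SAHA, for which the hypothesis had not been set, 21 were higher and 4 lower (median 0.44, camera p = 5.32e-09, and p = 0.038 with an estimated correlation). SAHA alone had lowered 18 of the 28 and raised 2.

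Ribosomal and small nuclear RNA genes summed to 17869 TPM in control replicate 2 and 31004 TPM in sonidegib replicate 3, and to between 4705 and 14195 TPM in the other 10 libraries. Among the 17 copies of 5S ribosomal RNA 9 were called higher with sonidegib. With all copies at 0 in the libraries without it, these calls cannot be credited to the drug. The most abundant gene was MT-CO2 in the control and SAHA libraries and AL669831.3 in 5 of the 6 libraries with sonidegib. In combination replicate 2 it was MT-RNR2.

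For some lists that camera did not call, the median, the mean and the test differed in sign, so no direction was given. An example was glycolysis with SAHA (median -0.25).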
